A study of Drosophila melanogaster with 2 samples.

How the data were processed

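The data were peak lists of a transcription factor ChIP-seq experiment on 2 biological replicates of whole Drosophila melanogaster embryos of 0 to 24 hours, from the ENCODE collection. Per the labels, the flies expressed a CG17612-eGFP fusion, chromatin was broken by sonication in a Bioruptor, and the immunoprecipitation used an anti-GFP antibody, while the antibody label itself names CG17612. A control experiment is named in the labels and was not analysed here. Both samples formed 1 group, with replicate numbers taken from the labels, which call them biological replicates.

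There were 8 lists, 4 thresholded and 4 ranked. Per the deposited description files, all are on the dm6 build, the pooled lists derive from the alignments of both samples and each sample's list from its own alignments, and 1 further alignment, whose role is not stated there, is common to all. The aligner, the peak caller and their versions are not given in the sources used here. The peak score is the authors' signal value in the deposited lists, with no stated scale, and a second score of each peak, scaled by the authors to at most 1000, was not used for any result. The ranked lists also hold the −log10 of the global IDR as deposited by the authors, which was at least 2.0 in every thresholded peak, in keeping with a threshold of 0.01. Ranked lists further hold the scores of the 2 peaks that were compared, in columns without a replicate name, called the first and second replicate column here. The ranked lists held 147450 (conservative), 149071 (less strict), 128242 (replicate 1) and 118490 (replicate 2) peaks, and the thresholded ones 2094, 2263, 1286 and 1347, of which 2042, 2207, 1255 and 1312 lay on the arms 2L, 2R, 3L, 3R, 4, X and Y. The pooled lists shared 1853 peaks with identical ends. No counts of reads are in the lists, so the depth of each library is unknown, and no interval on a score was computed.

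All choices of list, test, gene list, motif and distance were made before the data were examined, except where the text says otherwise. Coordinates are 1-based on dm6. The reference was the Ensembl release 115 annotation of BDGP 6.54 with the Release 6 genome, and the last peak end of each arm was checked to lie within the length of that arm. The annotation gave 18277 genes on the arms, 13968 of them protein-coding, and 24111 start sites over 137.5 Mb. Each summit was put in 1 class, in the order promoter (within 500 bp of a start site of any gene), 5′ UTR, coding exon, 3′ UTR, intron or non-coding exon, and intergenic. Chance shares came from 10000 circular shifts of the summits along each arm. Arm counts were tested with exact binomial tests against the arm's share of start sites and of length. Spacing and divergent start sites were tested against 10000 draws of start sites. Genes with a start site within 500 bp of a summit counted as bound, and each of 25 gene lists of at least 5 members was set against all other genes of its class with Fisher's exact test. Protein-coding lists were set against the other protein-coding genes, and tRNA and small nuclear RNA genes against all other genes. The lists were ribosomal protein, mitochondrial ribosomal protein, oxidative phosphorylation, proteasome, aminoacyl-tRNA synthetase, replication-dependent histone, insulator and architectural protein, Polycomb group, Trithorax group, Hox, early segmentation, dorsoventral and mesoderm, cell cycle and DNA replication, dosage compensation, piRNA and germline, heat shock and chaperone, neuronal, muscle structural, chemosensory receptor, cuticle protein, RNA polymerase II and general transcription factor, spliceosome, chromatin remodelling and heterochromatin, tRNA and small nuclear RNA genes.

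For motifs, the window of 50 bp on each side of the summit (101 bp) was compared with 1 flank window of the same size centred 300 bp away, on a side drawn once per peak, by an exact McNemar test over 12 consensus sequences. Words of 8 bases, both strands merged, were ranked on 2L and 3L, and the 50 with the lowest p were tested on 2R, 3R and X. Tests were two-sided with Benjamini-Hochberg adjustment within each family and a threshold of 0.05, except the one-sided overlap test. Intervals on shares are 95% Wilson intervals, and a share of 0 is given with the limit of 3 counts. The genes named were those nearest to the 20 strongest peaks of the conservative list, with a second gene where its start site on the other strand was within 500 bp, then up to 4 bound members of each list by score, then CG17612. The replicate scores of a named peak are those of the highest overlapping peak in each replicate's own ranked list.

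Alternatives fixed in advance were the less strict list, each replicate's own list, the higher-scoring peaks, start-site distances of 250 and 1000 bp, protein-coding start sites, uniform placement, ranked peaks as the chance set, circular shifts for gene lists, the nearest start site only, other overlap rules, windows of 100 bp on each side, start-site controls, and words of 6 and 10 bases. Added after seeing the data were the lists without the CG17612 region and without 81 peaks whose pooled score was under 0.5 times the sum of the replicate columns, start-site positions at the peaks' own offsets, promoter peaks against flanks, and 1000 shifts for gene lists in which the promoter peaks of an arm all move by the same number of start sites and keep their offsets. Left out of the comparisons were the 52 peaks on contigs outside the arms. The scripts were tested on simulated data. Uniform peaks gave a promoter call in 1 of 20 sets, random start sites a gene list call in 4 of 500 tests, and uniform windows a motif call in 1 of 120 and a word call in 0 of 500. Shifts along the order of start sites made 1 call in 250 tests of random start sites. A planted list of oxidative phosphorylation genes was recovered with no other call by Fisher's exact test and by these shifts, and a Su(Hw) core planted in 5% of 2042 windows was recovered by the motif test and by both of its words. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.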

Results

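Binding of CG17612 along the genome of Drosophila melanogaster was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole embryos collected 0 to 24 hours after egg laying. The flies carried a transgene that expresses CG17612 fused to enhanced green fluorescent protein (eGFP), and an antibody against GFP pulled down the fusion protein with its DNA. The samples were 2 biological replicates of 1 group, so the comparisons were between the replicates and between bound places and the rest of the genome, and no condition was compared with another. The files were peak lists without read counts, so the sequencing depth behind each peak is unknown. The conservative list of the 2 replicates together, thresholded on the irreproducible discovery rate (IDR), held 2094 peaks and covered 641 kb. Of these, 2042 lay on the 7 assembled chromosome arms and were used for the comparisons. Most peaks (1857 of 2094, 88.7%) were 324 bp wide, and 236 were narrower. Peak scores, which are the authors' and were used here to describe and rank peaks within a list, had a median of 98.0 and reached 1264. The 236 narrower peaks had a median score of 305, against 91.6 for those of 324 bp.

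Peaks of the replicates fell at the same positions far more often than shifted peaks did. Of the 1255 thresholded peaks of replicate 1 on the arms, 839 (66.9%, 95% Wilson interval 64.2 to 69.4) overlapped one of replicate 2 by at least 1 bp. Circular shifts of the peaks along each arm gave 0.535% ± 0.207 (SD over 1000 shifts). In the other direction, 835 of the 1312 peaks of replicate 2 (63.6%, 61.0 to 66.2) overlapped one of replicate 1, against 0.508% ± 0.194 after shifts. The one-sided permutation p was 0.001 both ways, the smallest that 1000 shifts can give. Among the 500 highest peaks of each replicate the overlap was 74.8%. The 416 peaks found in the thresholded list of replicate 1 alone had lower scores (median 55.5) than the 839 shared ones (83.6), and 387 of them (93.0%) lay under a peak of the ranked, unthresholded list of replicate 2, against 44.3% ± 2.42 (SD) after 200 circular shifts. The 477 found in replicate 2 alone had a median of 48.6 against 76.3, and 451 (94.5%) lay under a ranked peak of replicate 1, against 47.3% ± 2.37 after shifts. Across the 2042 peaks of the conservative list, the scores in the columns of the 2 replicates had a Spearman rho of 0.641, a description across peaks, which are not independent replicates. These peaks were chosen by IDR for agreement of the replicates, and over all 144329 ranked peaks rho was 0.2525. The relation was looser among the 1811 peaks of 324 bp (0.50) than among the 230 narrower ones (0.723). Intervals given here and below cover counting error only, since neighbouring peaks are not independent.

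**Figure D1:**
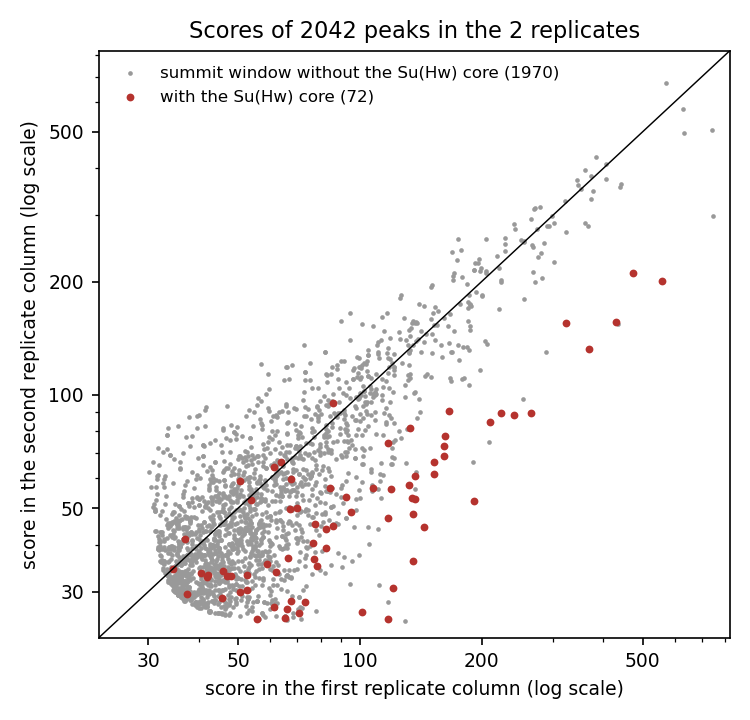
Scores of the 2042 conservative peaks in the first (x axis) and second (y axis) replicate column of the ranked list, both on log scales, with the line of equal scores. Red points are the 72 peaks whose 101 bp summit window holds the Su(Hw) core sequence, with a median ratio of first to second column of 2.09 against 1.09 for the 1970 grey points.

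The 20 strongest peaks lay at or near start sites of genes with varied roles. The highest score (1264) was at 2L:6612561-6612877, in an intron of CG11050 with its summit 1022 bp downstream of a start site, and the overlapping peaks of replicates 1 and 2 scored 741 and 505. Next came Ugalt, which encodes a UDP-galactose transporter (X:2703750-2704027, summit 37 bp upstream of the start site, score 1229, replicates 572 and 672). CG14100 followed (3L:19590476-19590745, 93 bp upstream, 1188, replicates 630 and 574), then mRpL41, a protein of the mitochondrial ribosome (2R:15217614-15217887, 130 bp upstream, 1127, replicates 631 and 496). The fifth peak was in an intron of ppk8, a member of the pickpocket family of sodium channels (X:3570399-3570677, score 1051, replicates 746 and 299). Between the divergent genes Art3, an arginine methyltransferase gene, and mRpS10 lay a peak of score 822 (3R:15229408-15229665), and the one between CG7601 and CIA30, an assembly factor of respiratory complex I, also scored 822. Other shared promoters were those of CG5611 and Mtl, a Rac-like GTPase (score 812), of Tcs5 and CHMP2B, an ESCRT-III subunit (747), of CenG1A and mRpS23 (723), of CG13390 and CG17294 (721), and of the antisense transcript asRNA:CR45928 and eIF6, a ribosome biogenesis factor (697).

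At ph-p, the Polycomb group gene polyhomeotic proximal, the peak lay in an intron 493 bp from a start site (X:2137232-2137467, score 783, replicates 406 and 374). The peak near the start sites of Chro and Ssl1 had its summit in the 5′ UTR of Chro (3L:22878786-22879019, score 693, replicates 352 and 353). Chro encodes the chromodomain protein Chromator, and Ssl1 a subunit of the general transcription factor TFIIH. PNPase, a mitochondrial polynucleotide phosphorylase, had its peak in the 5′ UTR (score 780), and Fkbp14, a peptidyl-prolyl isomerase of the endoplasmic reticulum, had one 115 bp upstream of a start site (643). The remaining strong peaks were in introns of CG9541 (761), of the transcription factor gene Adf1 (744), of CG32772 (713) and of kcc, a potassium-chloride cotransporter (679). In replicates 1 and 2 the CG9541 peak scored 557 and 201 and the kcc peak 473 and 211. Of the 20 peaks, 14 were within 500 bp of a start site and the other 6 were in introns. The summits at ph-p and Fkbp14, among the 14, were in introns as well.

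Promoters held about 3.6 times the share of peaks that chance placement gave. Summits within 500 bp of an annotated start site numbered 996 of 2042 (48.8%, Wilson interval 46.6 to 50.9), against 13.6% ± 0.896 (SD) after circular shifts, a 3.59-fold excess. Coding exons outside promoters held 61 summits (2.99% against 13.7% ± 0.927, 0.218-fold) and 3′ UTRs held 17 (0.833% against 4.43% ± 0.496, 0.188-fold). Intergenic sequence held 257 (12.6% against 27.3% ± 1.57, 0.461-fold). Introns and non-coding exons held 693, closer to their share of the genome (33.9% against 40.2% ± 1.38, 0.844-fold). For these 5 classes the two-sided permutation p was 0.0002, the smallest that 10000 shifts can give, and 0.00024 after Benjamini-Hochberg adjustment. The 18 summits in 5′ UTRs outside promoters were not distinguishable from shifted ones (0.881% against 0.783% ± 0.202, permutation test, adjusted p = 0.680). The median summit lay 538.5 bp from the nearest start site, 355 summits (17.4%) within 100 bp and 281 (13.8%) beyond 5 kb. The coding exon share was the least steady of the classes, at 0.0143-fold among the higher-scoring 1021 peaks, 0.0334-fold in the peaks of replicate 2 alone, 0.0932-fold in those of replicate 1 alone and 0.222-fold in the less strict list.

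**Figure D2:**
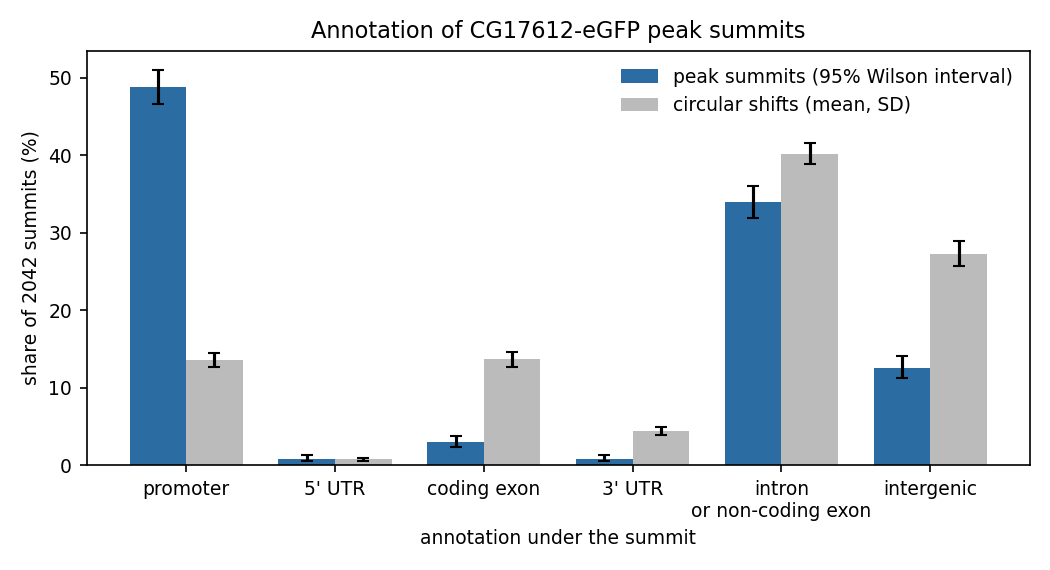
Share of the 2042 summits in each annotation class (blue bars, 95% Wilson interval) beside the mean of 10000 circular shifts (grey bars, SD), in percent. The promoter bar stands at 48.8% against 13.6%, and the coding exon bar at 2.99% against 13.7%.

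The X chromosome carried more peaks than its start sites would give, and chromosomes 2R, 4 and Y carried fewer. X held 391 peaks (16.6 per Mb), 1.17 times its share of annotated start sites (exact binomial adjusted p = 0.00234), and 2R held 367 (0.871 times, adjusted p = 0.00501). Chromosome 4, the small heterochromatin-rich chromosome, held 2 peaks (0.128 times, exact binomial adjusted p = 0.000259). The Y chromosome held 0 of 2042, which allows a share of up to 0.147% (exact binomial adjusted p = 0.000447). Whether reads can be placed uniquely along Y was not examined. Arms 2L (401 peaks, 1.01 times), 3L (424, 1.09 times) and 3R (457, 0.963 times) did not pass the test, with adjusted p of 0.758, 0.0887 and 0.435. Set against arm length, 2L (1.15 times, exact binomial adjusted p = 0.00631) and X (1.12 times, 0.0279) were above their share and 2R was not below it (0.978 times, adjusted p = 0.721). The shortfall on chromosome 4 did not pass in the peaks of replicate 1 alone (0.312 times, exact binomial adjusted p = 0.0573) or among the higher-scoring 1021 peaks (0.255 times, 0.0519), and that on Y did not in those of replicate 2 alone (0.163 times, 0.0673). Only 2 peaks or fewer are involved on chromosome 4 and Y in the conservative list. The binomial tests take peaks as independent, which neighbouring peaks are not, so their p can be too small.

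Peaks stood closer together than start sites drawn at random, and more often had start sites of genes on both strands nearby. The median distance between neighbouring summits was 25413.5 bp, against 32755 ± 1007 bp (SD) for 10000 draws of start sites from the same arms (0.776 times, permutation p = 0.0002). Of the 996 promoter peaks, 348 (34.9%, 32.0 to 37.95) had start sites of 2 genes on opposite strands within 500 bp, such as Art3 with mRpS10 or Chro with Ssl1. Start sites drawn at random had such a partner in 24.3% ± 1.32 of cases (1.44 times, permutation p = 0.0002). Both p are the smallest that 10000 draws can give. In each replicate's own list, which holds fewer peaks, the median distance was longer, 46.4 kb without replicate 2 and 42.5 kb without replicate 1, and again under that of drawn start sites (0.812 and 0.786 times).

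Ribosomal protein genes carried a peak at a start site most often of the 25 gene lists. Of 92 such genes, 33 (35.9%, Wilson interval 26.8 to 46.1) had a summit within 500 bp of a start site, against 8.51% of other protein-coding genes (odds ratio 6.01, Fisher's exact test, adjusted over the 25 lists p = 1.07e-11). The highest members were RpL7 (score 282, replicates 208 and 75.0, summit in the 5′ UTR at 2L:10200964-10201095), RpS27 (265, replicates 190 and 66.3), RpL34b (224, replicates 139 and 86.8) and RpL32 (167, replicates 107 and 57.6). The share depended on the replicate, at 32.6% (30 of 92, odds ratio 7.09) in the peaks of replicate 1 alone and 14.1% (13 of 92, odds ratio 2.66, Fisher's exact adjusted p = 0.0135) in those of replicate 2 alone. RNA polymerase II subunit, general transcription factor and mediator genes were the other list above the rest, with 12 of 64 (18.8%, 11.1 to 29.97, Fisher's exact test, odds ratio 2.44, adjusted p = 0.0469). Members were Polr2B, which encodes the second largest subunit of the polymerase (score 211), Taf5 of TFIID (181), Polr2H (159) and MED30 of the mediator complex (142). That call, close to the threshold, was lost at somewhat lower odds ratios with the less strict list (2.30, Fisher's exact adjusted p = 0.0611), in replicate 1 alone (2.04, 0.194), at 1000 bp (1.97, 0.126) and without 81 peaks whose pooled and replicate scores disagree (2.20, 0.0978). It was lost altogether when each peak was given only the gene with the nearest start site (4 of 64, 6.25%, odds ratio 1.01, Fisher's exact adjusted p = 1.00). Shifts of the promoter peaks along the order of start sites, a test chosen after the results were seen, called the list higher (4.77 genes expected, permutation adjusted p = 0.0375).

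A further 4 lists carried peaks less often than other genes. Chemosensory receptor genes, which encode odorant, gustatory and ionotropic receptors, had 0 of 179 (allowing up to 1.68%, Fisher's exact adjusted p = 1.69e-06). Cuticle protein genes had 0 of 117 (up to 2.56%, Fisher's exact adjusted p = 0.000265) and replication-dependent histone genes 0 of 111 (up to 2.70%, adjusted p = 0.000314). Transfer RNA genes had 5 of 290 (1.72%, 0.739 to 3.97, against 7.33% of other genes, Fisher's exact adjusted p = 0.000262), the strongest at tRNA:Tyr-GTA-1-8 (score 213), and 4 and 2 of 290 in the own lists of replicates 1 and 2. Members of these lists sit in clusters that can gain or lose a peak together, which Fisher's test does not see. Whether reads can be placed uniquely in repeated genes was not examined, so a share of 0 does not show absence of binding. Circular shifts of the peaks gave no call for the 4 lists (permutation adjusted p of 0.196, 0.517, 0.935 and 0.901 in the same order), but they move most peaks off start sites and expect only 2.83, 1.75, 1.73 and 4.05 bound genes, so a shortfall can hardly pass. Shifts of the promoter peaks along the order of start sites keep both the clustering and the number of peaks at start sites. These expected 8.91 chemosensory and 20.8 transfer RNA genes and called both lists lower (permutation adjusted p = 0.0167 for each), while cuticle genes (5.70 expected, 0.0599) and histone genes (9.20 expected, 0.121) did not pass.

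No call was made for 19 lists. Among them the largest shares were at heat shock and chaperone genes (5 of 22, 22.7%, Fisher's exact adjusted p = 0.116), with Hsp27 (score 317), Hsp83 (184), Hsc70-4 (123) and Hsp26 (100.2), and at insulator and architectural protein genes (5 of 22, 22.7%, adjusted p = 0.116), with Chro (693), Cp190, an insulator cofactor (231), Trl, the GAGA factor (168), and Dref, which binds the DNA replication-related element (131). Polycomb group genes had 3 of 18 (16.7%, Fisher's exact adjusted p = 0.459), namely ph-p (783), the histone methyltransferase gene E(z) (165) and Sfmbt (88.3). Small nuclear RNA genes had 5 of 32 (15.6%, Fisher's exact adjusted p = 0.195), with snRNA:U2:34ABb at 90.5. Mitochondrial ribosomal protein genes had 11 of 73 (15.1%, 8.63 to 25.0, Fisher's exact adjusted p = 0.167), including mRpL41 (1127), mRpS10 (822), mRpS23 (723) and mRpL23 (576). In the own lists of replicates 1 and 2 the bound members numbered 5 and 3 for the heat shock list, 4 and 3 for the insulator list, 2 and 2 for Polycomb, 0 and 4 for small nuclear RNA and 9 and 9 for mitochondrial ribosomal protein genes. The higher-scoring 1021 peaks marked 0 of 32 small nuclear RNA genes. Circular shifts, which leave few peaks at start sites, put these 5 lists and 2 more, aminoacyl-tRNA synthetase genes (4 of 32, 12.5%) and oxidative phosphorylation genes (7 of 84, 8.33%), above chance with permutation adjusted p from 0.01 to 0.0167. Shifts along the order of start sites called none of the 7 (permutation adjusted p from 0.117 to 1.00). Fisher's test put the last of these a little below other genes (odds ratio 0.955, adjusted p = 1.00). The heat shock list also passed Fisher's test within 250 bp (0.0462), within 1000 bp (0.00515), among the higher-scoring 1021 peaks (0.0231) and with the nearest start site alone (0.0401), and the insulator list within 250 bp (0.0462).

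Among the other housekeeping lists, SerRS (score 150), ThrRS (110), IleRS (101) and AspRS (82.5) were the bound aminoacyl-tRNA synthetase genes (Fisher's exact adjusted p = 0.741). ND-ASHI (236), ND-24 (152) and ND-MWFE (143) of respiratory complex I and COX5A (84.2) of complex IV led the oxidative phosphorylation genes. The proteasome list had 2 of 48 (Rpn3 at 173 and Rpt5 at 94.2, Fisher's exact adjusted p = 0.838), the spliceosome list 3 of 26 (SNRPG at 181, snRNP-U1-C at 99.2 and B52 at 98.1, adjusted p = 0.875) and the cell cycle list 2 of 36 (Dp, the partner of E2F, at 218 and the replication licensing gene dup at 102). Trithorax group genes had 2 of 16, brm, the ATPase of the Brahma remodelling complex (488), and skd (93.2). Chromatin remodelling and heterochromatin genes had 1 of 17 (Chd1 at 142), and piRNA and germline genes 2 of 16 (bgcn at 209 and cuff at 121). In lists of patterning and differentiation genes, early segmentation genes had 2 of 22 (nkd at 105 and bcd at 87.9), dorsoventral and mesoderm genes 1 of 16 (tin, the heart specification gene tinman, at 135), neuronal genes 1 of 21 (elav, an RNA-binding protein of neurons, at 313) and muscle genes 1 of 16 (sls, which encodes a titin-like protein, at 83.1). Hox genes had 0 of 8 and dosage compensation genes 0 of 5, too few to show a shortfall. From the cell cycle list onward each of these lists had an adjusted p of 1.00.

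**Figure D3:**
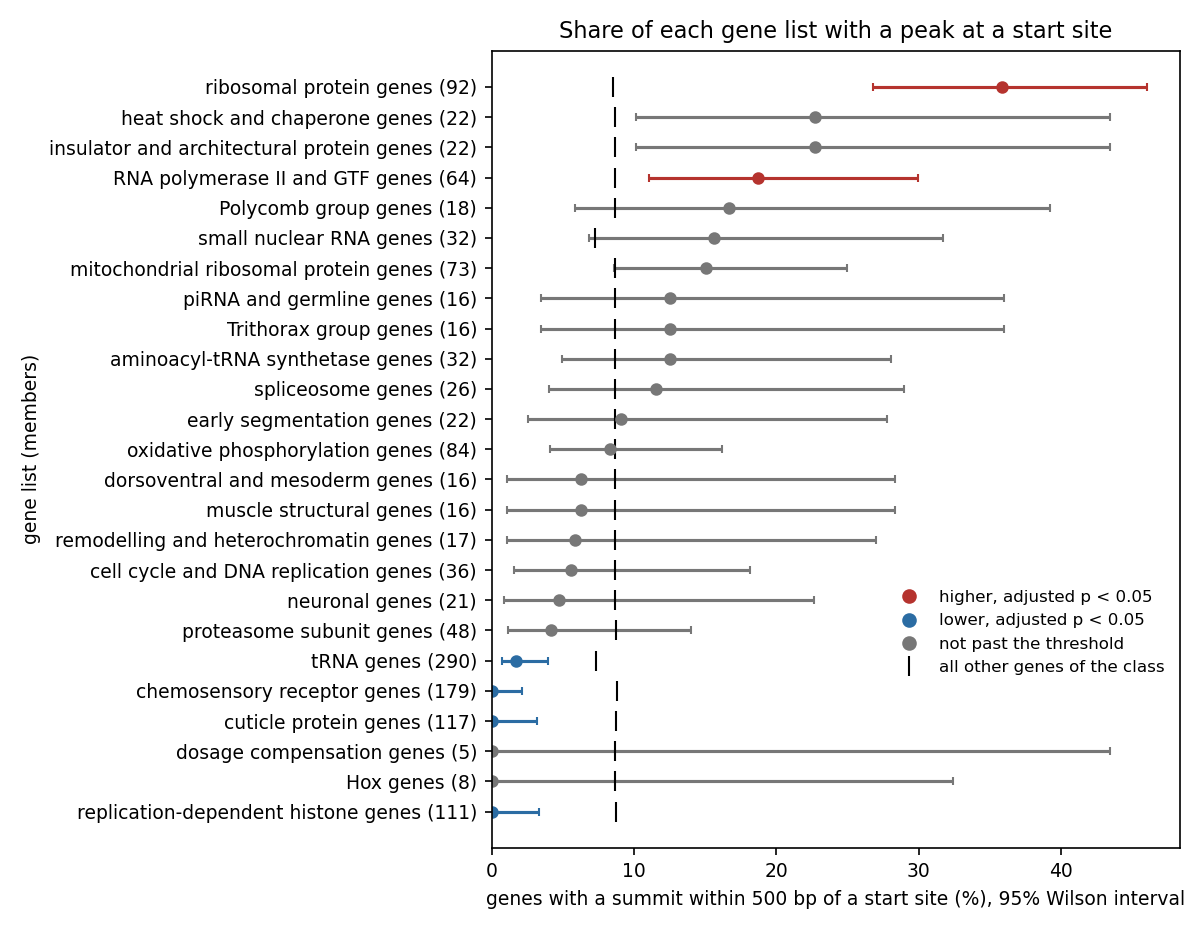
Percent of each of the 25 gene lists with a summit within 500 bp of a start site (points, 95% Wilson interval; list size in brackets), with the percent among other genes of the same class as a black tick. Ribosomal protein genes stand at 35.9% and chemosensory receptor, cuticle and histone genes at 0.

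Over all 2042 peaks against their flanks, the motif with the lowest p was the core of the Su(Hw) binding site. Su(Hw), suppressor of Hairy-wing, is a zinc finger protein of the gypsy insulator. Its core GCATACTTT, on either strand, lay in the 101 bp summit window of 72 peaks (3.53%, Wilson interval 2.81 to 4.42) and in the flank window of 6 (0.294%, exact McNemar test, adjusted over 12 motifs p = 2.22e-14). The core of the site of CTCF, another insulator protein, was in 33 summit and 9 flank windows (1.62% against 0.441%, exact McNemar adjusted p = 0.000546), Ohler motif 7 of core promoters in 194 and 128 (adjusted p = 0.000455), the TATA box in 120 and 77 (adjusted p = 0.00464) and the DRE, the site of Dref, in 23 and 8 (adjusted p = 0.0183). Fewer summits than flanks held the GAGA sequence bound by Trl (14 against 78, exact McNemar adjusted p = 9.40e-12) and the TCT initiator (202 against 263, adjusted p = 0.00621). The GAGA shortfall was smaller in windows of 100 bp on each side (65 against 118), and was 10 against 42 in the peaks of replicate 1 alone and 6 against 63 in those of replicate 2 alone. The initiator (180 against 211, exact McNemar adjusted p = 0.150), the E-box (72 against 95, 0.130), the Zelda site (7 against 9, 0.877), Ohler motif 1 (7 against 6, 1.00) and Ohler motif 6 (4 against 0, 0.150) did not pass. The Su(Hw) core passed in the lists of replicate 1 alone (5.74%) and replicate 2 alone (2.97%), and against ranked peaks at start sites (1.00% of 996 promoter peaks, exact McNemar adjusted p = 0.0234). At those 996 promoter peaks Ohler motif 7 had the lowest p instead, both against flanks (135 against 64, exact McNemar adjusted p = 8.15e-07) and against ranked start-site peaks (135 against 78, adjusted p = 0.00065).

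Several of the weaker motif calls missed the threshold in smaller sets of peaks, some with the ratio of summits to flanks little changed. In the peaks of replicate 2 alone Ohler motif 7 fell from a ratio of 1.52 to 1.06 (94 against 89, exact McNemar adjusted p = 0.832) and the DRE from 2.88 to 1.75, on few peaks (7 against 4, 0.659). In those of replicate 1 alone the TATA box (76 against 52, ratio 1.46 after 1.56, exact McNemar adjusted p = 0.0659) and the TCT initiator (124 against 153, 0.810 after 0.768, adjusted p = 0.105) did not pass at similar ratios, while the initiator was lower at summits (93 against 132, adjusted p = 0.0175). Among the higher-scoring 1021 peaks Ohler motif 7 (84 against 60, ratio 1.40, exact McNemar adjusted p = 0.0742) and the TCT initiator (93 against 125, 0.744, adjusted p = 0.0563) again missed the threshold at similar ratios, the DRE did so at a lower one (8 against 5, adjusted p = 0.697) and the E-box was lower (27 against 50, adjusted p = 0.0280). Promoter peaks set against their flanks gave no call for the CTCF core (15 against 6, exact McNemar adjusted p = 0.134) or the TCT initiator (100 against 118, 0.299), while against ranked start-site peaks the CTCF core passed (15 against 1, 0.00208). Set against ranked start-site peaks in place of flanks, GAGA (0.803%, 0.252) did not pass, the TCT initiator turned to slightly more frequent at summits (10.04% against 8.13%, 0.208), and the Zelda site (0% against 0.803%, 0.0188) and the E-box (3.71% against 6.02%, 0.0329) were lower. Summit windows were poorer in G and C than flanks, at 36.3% ± 11.1 against 43.3% ± 10.1 (SD over 2042 windows), and lower in 1406 pairs (68.9%). No control window was matched on base composition. Calls for sequences rich in A and T, or lower calls for those richer in G and C, may therefore follow in part from this difference, which was not tested.

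**Figure D4:**
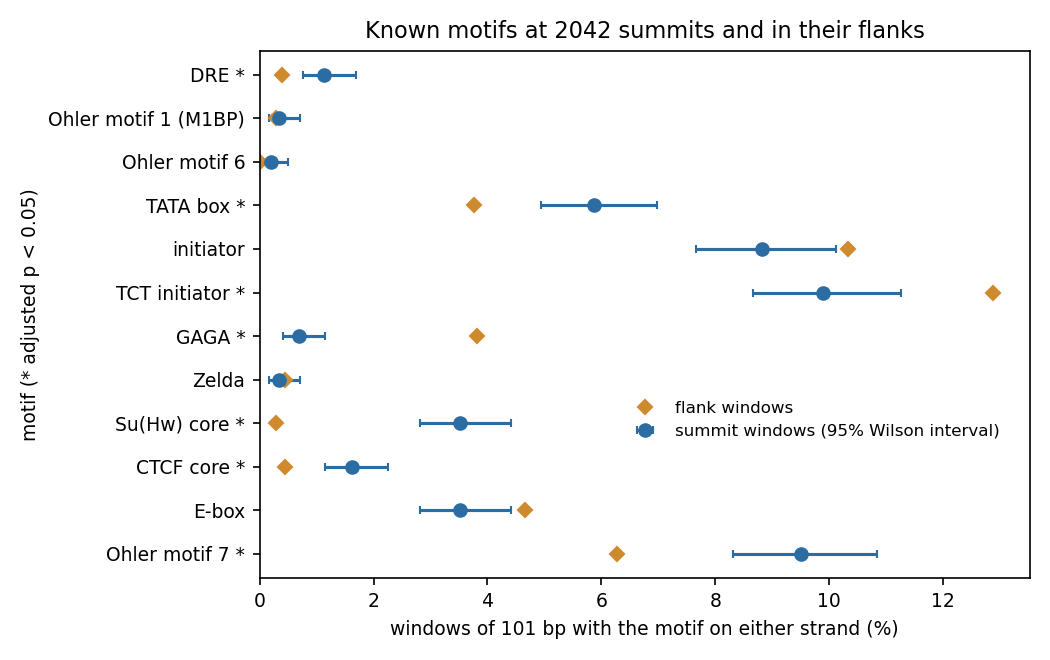
Percent of the 2042 summit windows of 101 bp (blue points, 95% Wilson interval) and of the flank windows (orange) that hold each of 12 known motifs. The Su(Hw) core stands at 3.53% against 0.294%, and GAGA at 0.686% against 3.82%.

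A search of all 8-base words, not matched on base composition, returned the Su(Hw) core and A/T-rich words. Of 50 words chosen on 2L and 3L (825 peaks), 32 passed on 2R, 3R and X (1215 peaks), 29 of them more frequent at summits, 20 of these made only of A and T. Words of A and T alone may pass because summit windows were poorer in G and C than flanks. The leading word was AAAGTATG, in the summit window alone of 61 held-out peaks and the flank alone of 7 (exact McNemar adjusted p = 3.69e-10), followed by AAGTATGC (59 against 7, adjusted p = 5.96e-10), both parts of the Su(Hw) core read on the other strand. The 3 words lower at summits were AGAGAGAG (7 against 27), GAGAGAGA (5 against 22) and CAGCAGCA (7 against 31). AAAGTATG was more frequent at stronger peaks, in 7.33% (5.19 to 10.3) of the 409 peaks with the highest scores, then in 5.15%, 3.91% and 2.70%, and in 1.47% (0.676 to 3.17) of the 408 with the lowest. These are pooled scores, and peaks with the core scored higher in the first replicate column (median ratio 2.09, against 1.09 for other peaks). The trend by each replicate's own score is not given here. Its 84 occurrences lay a median of 21.5 bp from the summit, near the 23.5 bp that uniform placement in the window would give. The strongest peaks with the core were in introns of CG9541 (2L:8973115-8973123) and kcc (2R:23912038-23912046), at scores of 761 and 679. Peaks with the core were at promoters less often than other peaks, 10 of 72 (13.9%) against 986 of the other 1970 (50.1%, Fisher's exact p = 3.65e-10). Their share was near the 13.6% that circular shifts of all 2042 summits gave, so it shows no shortfall against chance placement. In the peaks of replicate 2 alone the leading word was TATTTTAA, and 1 word sharing the core passed, against 4 in the conservative list. With the discovery and test arms swapped it was ATTTAAAA (65 against 20), and with 6-base words TTAAAA (310 against 123). A word sharing the core led in the other alternatives.

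CG17612 itself, the tagged gene (2L:4380722-4382735, minus strand), had no summit within 500 bp of its start sites in any of the 4 thresholded lists. Within 20 kb of the gene lay 6 peaks of the conservative list with scores of 23.2 to 80.7, ranking 1399 to 1972 of 2042. The peak of score 23.2 overlaps that of score 78.5, so these are not 6 separate places. Windows of the same 42.0 kb along the arms held 0.623 peaks on average, and 10 of 3278 (0.305%) held as many as 6. The less strict list had 10 peaks there, reached by 1 of the 3278 windows, and replicate 2 had 5, reached by 10 of them. Replicate 1 had 1, as many as 860 windows (26.2%), so its thresholded list shows no cluster. Extra copies of this sequence in the transgene can raise scores at the locus, so peaks here were counted but not read as binding.

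**Figure D5:**
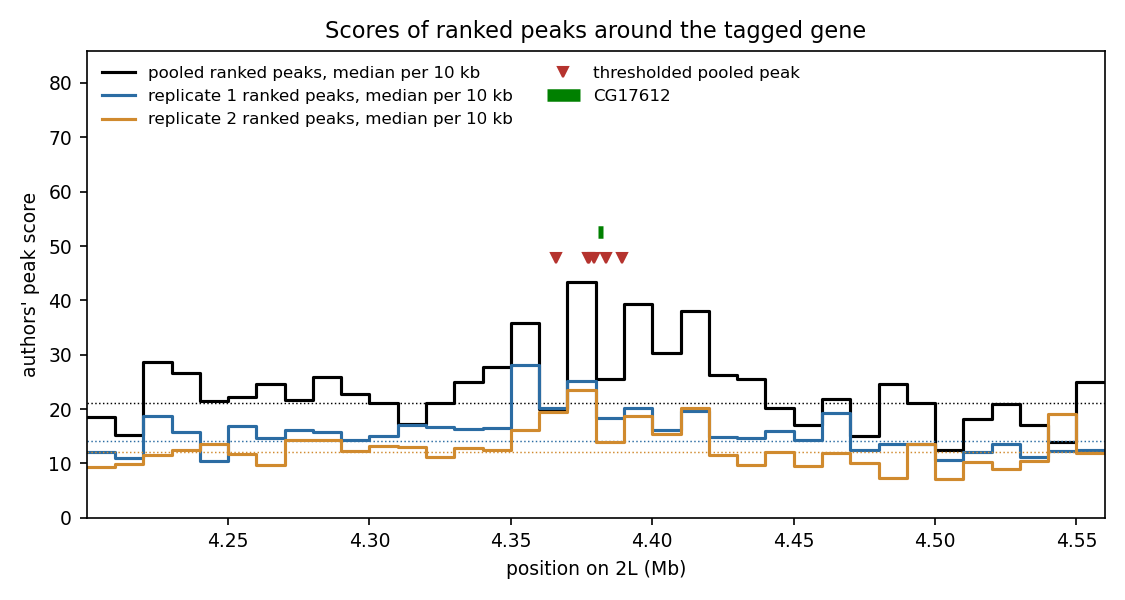
Median score of ranked peaks per 10 kb of 2L (x axis, Mb) around CG17612 for the pooled list and for replicates 1 and 2, with dotted lines at each list's median. Red triangles mark only the thresholded pooled peaks within 20 kb of the gene, and those further out are not drawn. These 6 conservative peaks lie between 4365635 and 4389503.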

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

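The counts below come from peaks that no comparison used. They were looked at only after the results were seen, and neither their size nor an explanation was tested.

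Peaks outside the assembled arms were not part of the comparisons. The conservative list held 52 such peaks on 48 contigs, all assigned to X, and their median score of 92.2 was near the 98.2 of peaks on the arms. Of the 3121 ranked peaks on contigs, 923 were on X-assigned ones.

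The ranked pooled list held 97 peaks at or under the IDR threshold of 0.01 that the conservative list lacks. Of these, 69 were on the arms, with 35 on 3R and 17 on 2L, and 28 were on contigs. Their median score was 97.6. The strongest, at 2L:480950-481231, had a score of 977 and was the sixth highest of the ranked list, 1392 bp from the nearest start site, that of cbt, which encodes the zinc finger protein cabut. This peak was singled out after its values were seen.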

How the results depend on the processing

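The lists without the CG17612 region and without 81 peaks of low pooled score, the start-site positions at the peaks' own offsets, promoter peaks against flanks, and shifts along the order of start sites were chosen only after the results were seen. Of 543 values recomputed under an alternative, 498 were labelled the same, 23 fell below the threshold, 16 rose past it, 3 counts moved and 3 values reversed. The same means an unchanged call, no call in both settings whatever the direction, or a count or rho near its main value. Of the 351 that answer a comparison directly, 325 were the same. The promoter share ranged from 38.3% (within 250 bp) to 60.6% (within 1000 bp), the share of divergent promoters from 28.2% to 38.4% and the replicate overlap from 58.2% (replicate 2 in replicate 1) to 74.8%, each past its test. The ribosomal protein list passed under 11 of 11 alternatives (14.1% to 38.04%) and the Su(Hw) core under 9 of 9 (1.00% to 5.74%), while the RNA polymerase II list failed under 5 of 11: the less strict list and 1000 bp (18.8% in both), without the 81 peaks (17.2%), without replicate 2 (12.5%, against 14.1% without replicate 1) and nearest start site (6.25%). The heat shock list rose past the threshold among the higher-scoring 1021 peaks, within 250 bp, with the nearest start site and with circular shifts (22.7% each) and within 1000 bp (36.4%), and the insulator list within 250 bp and with circular shifts (22.7% both). Circular shifts, but not shifts along the order of start sites, raised the mitochondrial ribosomal protein (15.1%), aminoacyl-tRNA synthetase (12.5%), Polycomb (16.7%) and small nuclear RNA (15.6%) lists past the threshold, and circular shifts lost the call for the histone (0%), chemosensory (0%) and cuticle (0%) lists. Shifts along the order of start sites lost it for the histone (0%) and cuticle (0%) lists. Words that passed fell from 32 (29 of them higher at summits) to 5 with 10-base words (5 higher), 20 with the discovery and test arms swapped (19 higher) and 18 with start sites as control (18 higher). Circular shifts reversed the oxidative phosphorylation list (8.33%) and the tRNA list (1.72%), since a shifted peak rarely meets a start site, so the chance share is lower. The TCT initiator reversed at promoter peaks against ranked start-site peaks (10.04% against 8.13%), which comes with that control, since against flanks the same peaks stayed lower without a call (11.8% in flanks). No paired analysis was possible because the samples form 1 group. Depth is unknown, so a gene without a peak cannot be told from one with too few reads, and 2 replicates in 1 group give no test between conditions.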

Other observations

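Except for the one on base composition, the tests below were chosen only after the result they bear on was seen, and with 1 group in the design no biological explanation was tested.

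Narrower peaks were at promoters more often than those of 324 bp. Of the 230 narrower peaks on the arms, 143 (62.2%) were at promoters, against 853 of 1811 (47.1%, Fisher's exact p = 1.79e-05). Mitochondrial ribosomal protein genes had 6 of 73 members under a narrower peak (odds ratio 7.23, Fisher's exact p = 0.000311, not adjusted) and 5 under a common-width one (odds ratio 0.903). Ribosomal protein genes of the cytoplasm had 2 of 92 under a narrower peak (odds ratio 1.75) and 31 under a common-width one (odds ratio 6.41). The difference between the 2 kinds of peak was not itself tested for these lists. In the whole conservative list the narrower peaks also scored higher (median 305 against 91.6). No comparison at like score was made, so width cannot be told apart from score here.

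Peaks with the Su(Hw) core lay mostly away from promoters, at a promoter share near that of shifted summits. After CG9541 and kcc, the strongest were near TP53INP (3L:4410428-4410436, intron, score 575), lncRNA:CR46039 (3R:19187779-19187787, intron, 510.0), v, the tryptophan oxygenase gene vermilion (X:10921837-10921845, 3′ UTR, 477), and if, the integrin gene inflated (X:16767263-16767271, intron, 356). In replicates 1 and 2 the TP53INP peak scored 429 and 156 and the v peak 324 and 155. These genes were chosen by the motif after the values were seen.

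Peaks with the Su(Hw) core had unequal scores in the replicates, with a median ratio of first to second column of 2.09 (log2 1.06, n = 72) against 1.09 (log2 0.13, n = 1970) for other peaks, a log2 difference of 0.93 (permutation p = 0.0002, the smallest given by the 10000 permutations). A general difference in depth or scale is argued against, since peaks matched on pooled score left a log2 difference of 0.97 (95% of draws 0.85 to 1.08), and so is base composition, since matching on it as well left 1.00 (0.90 to 1.09). Fragments of another library in 1 replicate only, as the sole source of peaks with the core, are argued against too, since the core was enriched at summits in the own lists of replicate 1 (72 of 1255) and replicate 2 (39 of 1312), the larger adjusted p being 4.70e-09. The shares in these lists differed (Fisher's exact p = 0.000634). Both that test and the permutation test take peaks as independent, though each replicate is 1 library and the 2 lists share many positions. Neither p measures variation between replicates. Foreign fragments in 1 replicate on top of binding in both, foreign fragments in both in unequal amounts, or embryo collections of different stages, may account for the pattern and were not tested.

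The cluster of peaks around CG17612, seen in the pooled lists and that of replicate 2 but not among the thresholded peaks of replicate 1 (1 peak within 20 kb), may come from extra copies of the locus carried by the transgene. Under that hypothesis the whole region would be raised. The lower quartile of ranked-peak scores within 40 kb of the gene was 1.49 times the median of windows in the pooled list, 1.36 times in replicate 1 and 1.41 times in replicate 2, at or above percentile 99.28 in each list. The rise was uneven. Of 7 bins of 10 kb in the window, each with 9 to 19 ranked peaks, 6 had a median above that of the pooled list and 2L:4360001-4370000 was at 0.952 times it, while 7 of 7 were above in each replicate. Many bins outside the window were above the pooled median of 21.1 too, such as 2L:4220001-4230000 (28.6) and 2L:4340001-4350000 (27.7). Others were below it, such as 2L:4500001-4510000 (12.4). The count of raised bins therefore does not by itself set the window apart. The bin with CG17612 itself was at 1.21 times in the pooled list, 1.30 times in replicate 1 and 1.16 times in replicate 2, the lowest of the 7 or the next to lowest in each, and extra copies alone do not predict that. Ranked peaks there that were not thresholded also had high medians, at or above percentile 99.55 of windows. They were 118 of the 119 ranked peaks in replicate 1 and 115 of 125 in the pooled list, so thresholded pooled peaks were not confined to the 20 kb around the gene. A ranked peak under the threshold can still be a binding site, so these medians cannot tell separate sites from a rise of the whole region. Separate binding sites and local chromatin that raises scores over the same span both stay open.

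The excess of peaks at ribosomal protein genes is argued not to come from the number and spacing of their start sites, since shifts of the promoter peaks along the order of start sites found 8.62 such genes on average against 33 observed (permutation adjusted p = 0.0167). Recovery common to housekeeping start sites in general stays open. The 6 other housekeeping lists together (mitochondrial ribosomal protein, oxidative phosphorylation, proteasome, aminoacyl-tRNA synthetase, RNA polymerase II and spliceosome) had 39 of 327 genes bound, an odds ratio of 1.44 (95% interval 1.02 to 2.02) against 6.01 (3.91 to 9.24) at ribosomal protein genes. The intervals were also apart in replicate 1 alone (0.993 to 2.13 against 4.56 to 11.03), but in replicate 2 alone they overlapped (0.930 to 2.10 against 1.48 to 4.81). Bound ribosomal protein genes numbered 30 in replicate 1 and 13 in replicate 2, and the highest named members scored higher in replicate 1. Whether this imbalance shares a source with that of peaks with the Su(Hw) core was not tested. Recovery that grows with transcription could still contribute, and no expression values were used here.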
